A study of Homo sapiens with 18 samples.

How the data were processed

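Messenger RNA was measured on 18 one-colour 3' expression arrays with 54675 probe sets, of which 62 were control probe sets. The arrays covered 6 groups of 3: untransfected DAOY medulloblastoma cells, a clone with the empty vector (V11), 2 clones with a MYC expression vector (M2 and M14), and M2 cells transfected with non-targeting siRNA or with siRNA against MYC. Groups were taken from the labels. The deposited values are intensities on a linear scale, summarised per probe set with RMA (version not given), per the submitters' processing notes. Whether the authors normalized all arrays together is not given in the sources used here.

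The design had been fixed for log2 values that share 1 distribution. The values were linear, and the arrays did not share a distribution. Sorted log2 values differed by a mean of 0.00391 to 0.0657 between arrays of the same group, by 0.0283 to 0.0724 between wt and M14 arrays, and by 0.0133 to 0.0269 between the siRNA groups. For all other pairs of groups the difference was 0.15 to 1.1. The arrays therefore look normalized in 4 separate sets, with wt and M14 in one, both siRNA groups in another, and V11 and M2 each in its own. Values were log2-transformed and quantile-normalized across all 18 arrays, which had been planned as an alternative and became the main setting once the array distributions had been seen, before any gene was tested. Silencing and M14 against wt lie within a set. M2 against V11, M14 against V11, M14 against M2, V11 against wt and scrambled siRNA against M2 cross sets, so in these a difference in how the sets were normalized cannot be told apart from a change shared by most genes.

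Quantile normalization sets the median gene near 0 by construction. Other scalings moved it. In the deposited values, the median log2 difference over all genes was -0.593 in M2 against V11, -0.144 in M14 against V11, 0.44 in M14 against M2, 0.161 in V11 against wt and 1.13 in scrambled siRNA against M2. With each array centred on its hybridization controls, it was 0.321 in M14 against V11, -0.257 on silencing, 0.313 in M14 against M2 and 0.496 in scrambled siRNA against M2. With each array centred on its median, it was -0.132 in M14 against M2 and -0.135 in scrambled siRNA against M2. These 3 scalings differ from each other by 1 constant per array. All changes are reported relative to the median gene of the quantile-normalized values.

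Of the probe sets, 41091 were paired with 1 gene symbol, 1801 with several and 11721 were not listed with a gene. Only those with 1 symbol were named, and the gene identifiers of 41037 matched the table of current gene names. A gene was represented by its brightest probe set, which gave 19775 genes. The 14178 genes above the 50th percentile of all values (5.346 on the log2 scale) on at least 3 arrays were tested. Groups were compared with limma 3.58.1 in R 4.3.3, with 1 model over all 18 arrays and moderated statistics. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and adjusted p-values of single genes are from this test. No replicate number was used as a block. The replicate numbers are not stated to mark a shared culture or day.

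The 32 gene lists were fixed before the data were examined. Some share members, so their results are not independent of each other. Direct MYC targets share FBL, DKC1, BOP1, PPAN and LYAR with ribosome biogenesis, and the hypoxia response shares SLC2A1, PDK1 and PFKFB4 with glycolysis. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives, adjusted over the 32 lists of a comparison. Named genes followed a rule fixed before the data were examined: the 6 largest rises and 6 largest falls in the comparisons of each clone with V11 and on silencing, and 4 of each in the others, among called genes whose groups did not overlap; up to 2 members per direction from each list described; 9 genes of the MYC and BMP families; and the 6 genes per direction that moved most in both clones and oppositely on silencing. Y-linked genes, XIST and uncharacterised genes were left out. Lists about MYC and BMP signalling, chosen by the title of the study, were described in each main comparison, with every list that passed camera there.

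The model was tested on simulated data for the 14178 genes, with the spread of each group as measured. Changes of 1 log2 were found for 98% of 50 genes in M2 against V11, 98% in M14 against V11 and 100% on silencing. Changes of 0.5 log2 were found for 56%, 68% and 70%, and changes of 0.25 log2 for 6%, 20% and 0%. False calls made up 18.2% of calls in M2 against V11 and 47.6% in M14 against V11, above the intended 0.05 share, and 0% on silencing. With an equal spread in all groups the shares were 2.24%, 3.12% and 3.73%. With only the arrays of the groups compared they were 7.26%, 11% and 4.97%, and with 1 weight per group 15.4%, 20.3% and 14.1%. Few genes were simulated as changed, so a share of false calls here does not carry over to comparisons with many changed genes; of unchanged genes 0.207%, 0.93% and 0% were called. False calls of at least 1 log2 numbered 2, 3 and 0. Counts of genes that differ by at least 1 log2 are therefore given beside the counts of each comparison of 2 groups. The number of arrays limits the precision.

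The alternatives were another filter or none, the mean of all probe sets of a gene, each probe set on its own, a minimum difference of 1 log2, eBayes with trend and robust settings, only the arrays compared, a replicate block, wt in place of V11, centring on hybridization controls, and leaving out each array in turn. Chosen after seeing the data were the deposited values without quantile normalization, centring on the median, 1 weight per group, the other 3 BMP7 probe sets, and wt in place of V11 for lists.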

Results

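The study asked whether BMP7, a secreted bone morphogenetic protein, responds to the transcription factor MYC in medulloblastoma, a childhood brain tumour. Gene expression was measured in DAOY, an established medulloblastoma cell line. The 18 arrays fell into 6 groups of 3: untransfected cells (wt), an empty-vector clone (V11), the MYC-transfected clones M2 and M14, and M2 cells given 50 nM of non-targeting siRNA (scrambled) or of siRNA against MYC (silenced). The clones were kept under 500 µg/ml G418. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The labels also do not give the time after transfection at which the array RNA was taken. Levels of groups in separately normalized sets are set side by side after quantile normalization only, and n is 3 arrays in each group throughout. Where the level of a group lies below 5.346 log2, the median of all values, its signal may be background, and the size of a difference then depends on that background.

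MYC, the targeted gene, was followed in every group first. Its level was 9.44 log2 units in wt, 8.36 in V11, 10.40 in M2, 11.16 in M14, 11.35 in scrambled and 9.34 in silenced arrays. MYC was 2.03 ± 0.24 log2 units (SE) higher in M2 than in V11 (adjusted p = 4.6e-06) and 2.80 ± 0.24 higher in M14 than in V11 (adjusted p = 8.7e-08). Against wt, the differences were 0.96 and 1.72. Silencing lowered MYC, with a difference of -2.00 ± 0.24 (adjusted p = 2.78e-06). Whether its probe set detects the MYC transgene as well as the cells' own MYC is not given in the sources used here, so these are levels of that probe set. The V11 arrays ranged from 7.72 to 8.92. Without V11 replicate 2 the difference of M2 from V11 was 1.71, and that of M14 from V11 was 2.47.

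BMP7 moved the same way as MYC in all 3 main comparisons, but its brightest probe set did not in the 3 others. There MYC differed by -1.08 in V11 against wt, 0.76 in M14 against M2 and 0.95 in scrambled siRNA against M2. That probe set differed by -0.06, -0.39 and -0.04, while 2 of the 3 other BMP7 probe sets rose in the last 2 of these. The brightest BMP7 probe set had a level of 6.68 in wt, 6.62 in V11, 8.19 in M2, 7.80 in M14, 8.15 in scrambled and 6.81 in silenced arrays. It was 1.57 ± 0.11 log2 units higher in M2 than in V11 (adjusted p = 2.19e-08) and 1.18 ± 0.11 higher in M14 than in V11 (adjusted p = 1.73e-07), and silencing changed it by -1.34 ± 0.11 (adjusted p = 3.98e-08). Of the 3 other BMP7 probe sets, 2 moved the same way, by 1.11 and 0.36 in M2, 3.20 and 1.55 in M14, and -1.39 and -0.98 on silencing. The remaining one differed by 0.11 in M2 (adjusted p = 0.368) and 0.13 in M14 (adjusted p = 0.303), and by -0.32 on silencing (adjusted p = 0.0184). The 2 that moved were higher on M14, scrambled and silenced than on wt, V11 and M2 arrays. The first had 8.35, 8.61 and 7.22 against 5.16, 5.16 and 6.27. The 3' and 5' ends of ACTB differed by 0.22, 0.09 and 0.11 on the former, against 0.47, 0.42 and 0.53. The rise of these 2 in M14 therefore cannot be told apart from a difference in RNA or labelling. BMP6, a related ligand, was 3.84 ± 0.17 higher in M2 and 4.07 ± 0.17 higher in M14 than in V11, and fell by 0.79 on silencing. Its level was 4.77 in V11 and 4.87 in wt, below 5.346. It was at -0.85 in scrambled siRNA against M2, where MYC was higher. The 2 other BMP6 probe sets differed by -0.12 and 0.24 in M2 and by -0.22 and 0.03 in M14, none past the test. BMP2 was 0.92 and 1.47 higher in the clones and fell by 0.53 on silencing. Of 13 pro-survival regulators, 4 rose and 4 fell in M2 (camera adjusted p = 0.997), and 5 rose and 5 fell in M14.

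**Figure D1:**
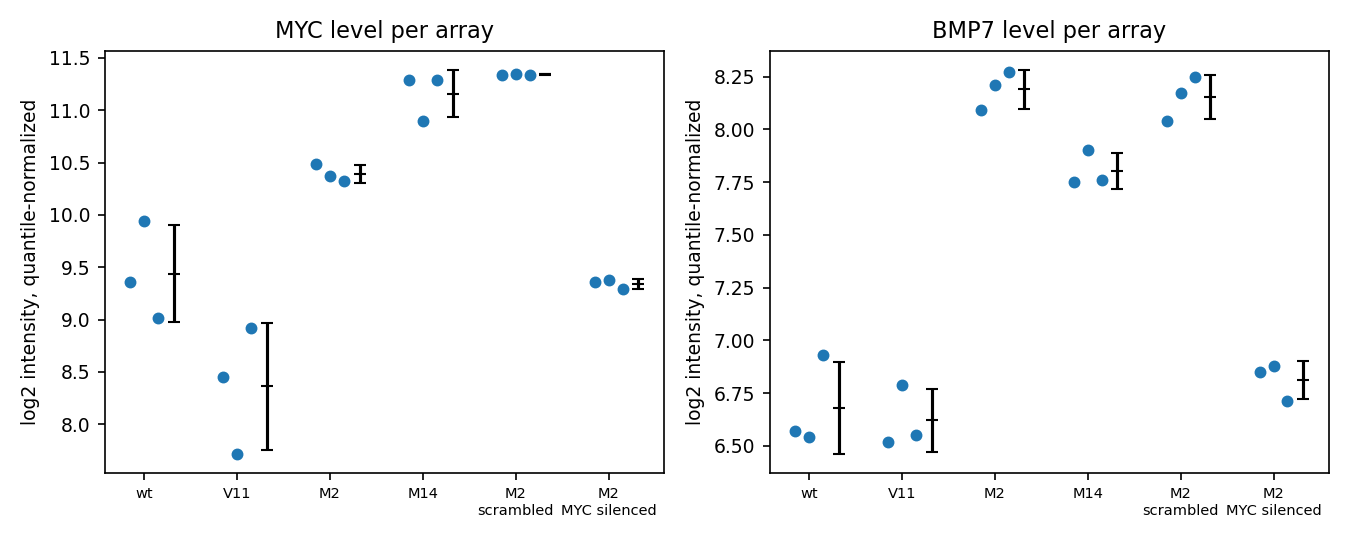
Quantile-normalized log2 intensity of MYC and BMP7 on each of the 18 arrays (points), with the mean and SD of the 3 arrays of each group (bars). MYC was lowest in V11, at 8.36, and highest in scrambled M2 cells, at 11.35. BMP7, shown by its brightest probe set, was between 6.62 and 6.81 in wt, V11 and silenced cells. In 2 other probe sets silenced cells lay above wt and V11, at 7.22 against 5.16 and 5.16, and 6.69 against 5.94 and 5.78. In the remaining one they lay lower, at 6.35 against 6.81 and 6.76.

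M2 against V11 compared 1 MYC-transfected clone with 1 empty-vector clone. An effect of MYC therefore cannot be told apart from other differences between these clones. For scale, 5163 genes changed between V11 and wt, and 7797 between the MYC-transfected clones M14 and M2. NELL2, a secreted neural protein, was 4.82 ± 0.13 log2 units higher in M2 and CYYR1 was 4.54 ± 0.11 higher, followed by the lactate and pyruvate transporter SLC16A7 (4.30), the neuropeptide precursor TAC1 (4.26), DCAF4L2 (4.14) and FRMD3 (4.06). Lower were the cancer-testis antigen MAGEA8 (-6.19 ± 0.12), the guidance molecule SEMA3C (-4.24), the smooth muscle coactivator MYOCD (-4.07), the fibrillar collagen genes COL3A1 (-3.93) and COL1A2 (-3.89), and GASK1B (-3.79). Against wt, MAGEA8 differed in M2 by -0.27 and GASK1B by -0.11, neither past the test. These genes were 5.92 and 3.68 higher in V11 than in wt. NELL2 was 0.80 higher in M2 than in wt. Levels lay below 5.346 in V11 for NELL2, CYYR1, SLC16A7, TAC1 and DCAF4L2, and in M2 for MAGEA8, MYOCD and GASK1B.

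Among 32 direct MYC targets measured, 23 were higher in M2 and 1 lower, and adjusted over the list alone the counts were the same. The telomerase gene TERT rose by 1.29 and the RNA polymerase III subunit POLR3G by 2.16, while the cell cycle kinase CDK4 fell by 0.44. The median of the list was 0.42 (camera adjusted p = 5.89e-05; adjusted p = 0.719 with an estimated correlation). Of 34 genes of the mitochondrial ribosome and protein import, 22 rose and none fell, among them MRPS30 (1.27) and MRPS2 (0.85), with adjusted p = 0.719 with an estimated correlation. Of 24 nucleotide synthesis genes, 12 rose and 2 fell. The purine enzymes PAICS and PPAT rose by 1.05 and 1.31, and IMPDH2 fell by 0.25 but was 0.56 higher in M2 than in wt. The estimated correlation gave adjusted p = 0.719. Of 43 ribosome biogenesis genes 20 were higher and 8 lower, or 21 and 9 adjusted over the list alone, while against wt 21 were higher and 1 lower (median 0.243; camera adjusted p = 0.00124; adjusted p = 0.614 with an estimated correlation). WDR12 and FBL rose by 0.84 and 0.62, while IMP4 was at -0.83 and FTSJ3 at -0.84, although IMP4 differed by 0.24 against wt (adjusted p = 0.0807); the list had adjusted p = 0.789 with an estimated correlation. Of 34 mitosis genes, 16 rose, among them the kinases BUB1 (0.81) and AURKA (0.72), and HMMR fell by 0.75 (adjusted p = 0.719 with an estimated correlation). Of 19 cholesterol synthesis genes, 10 rose, among them NSDHL (0.89) and MVD (1.22), and 2 fell, PMVK (-0.56) and TM7SF2 (-1.07) (adjusted p = 0.719 with an estimated correlation).

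TGF-beta response and matrix genes were lower in M2, with 20 of 35 down and 3 up, or 21 and 4 adjusted over the list alone. The collagen gene COL5A2 was at -3.40 and the smooth muscle actin gene ACTA2 at -2.62, while TIMP3 and CCN3 rose by 1.51 and 1.58 (list adjusted p = 0.719 with an estimated correlation). Of 16 fibroblast and smooth muscle markers, 8 fell, among them the proteoglycan gene LUM by 3.18, and TWIST2 rose by 0.86. The estimated correlation gave adjusted p = 0.419, and against wt the list did not pass camera (adjusted p = 0.243). Other lists about the subject did not pass camera. In the MYC network, MXI1, an antagonist of MYC, rose by 1.48 with 5 of 11 members up; MAX, its partner, rose by 0.47 but differed by -0.29 against wt (adjusted p = 0.134). Of 19 MYC-repressed genes 4 rose and 5 fell, or 6 and 6 adjusted over the list alone, among them ITGB5 (0.61), ITGA6 (0.76), PDGFRB (-1.15) and ITGA1 (-0.78). Of 31 BMP ligands, receptors and antagonists 9 rose and 5 fell, or 8 and 5 adjusted over the list alone, with BMP5 at -2.40 and SMURF1 at -0.83. Of 18 BMP response genes 8 rose and 2 fell, with GATA2 at 1.34, MSX1 at 0.60, SKIL at -0.54 and ID1 at -0.64. Against wt 10 rose and none fell (camera adjusted p = 0.141), and ID1 differed by -0.05 (adjusted p = 0.821). ID2 differed by -0.09 from V11 (adjusted p = 0.764) but was 0.65 higher in M2 than in wt (adjusted p = 0.0344), and ID3 differed by -0.21 from V11 (adjusted p = 0.215) and by 0.23 from wt (adjusted p = 0.188). In all, 7607 of 14178 genes passed the test, 3813 higher and 3794 lower, of which 421 and 620 by at least 1 log2. The share of higher calls was 50.1%, and 5.06% in the deposited values without quantile normalization. The arrays of both groups did not overlap for 60.1% of genes, against 10% by chance.

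M14 against V11 compared the second clone in the same way, with the same limit. The kisspeptin receptor gene KISS1R was 5.23 ± 0.35 higher in M14, the chemokine receptor gene CXCR4 4.83 ± 0.21, the imprinted gene PEG3 4.81 ± 0.19 and the glutamate transporter gene SLC1A6 4.74 ± 0.32, followed by FRMD3 (4.70) and NELL2 (4.63). Lower were SEMA3C (-6.03 ± 0.18), GASK1B (-5.50), the decoy receptor gene IL13RA2 (-5.47), MYOCD (-5.08), MAGEA8 (-4.97) and MAGEB2 (-4.80). Against wt, CXCR4 was 0.84, NELL2 0.61 and MAGEA8 0.95 higher in M14. Levels lay below 5.346 in V11 for KISS1R, CXCR4, SLC1A6 and NELL2, and in M14 for SEMA3C, GASK1B, MYOCD, MAGEA8 and MAGEB2.

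Genes of low oxygen and sugar breakdown led the lists. Of 20 hypoxia response genes, 19 were higher in M14, among them the carbonic anhydrase CA12 (3.39) and the mitophagy gene BNIP3 (2.34), with a list median of 1.79 (camera adjusted p = 2.66e-08; adjusted p = 0.24 with an estimated correlation). Of 22 glycolysis genes, 18 rose and none fell, among them GPI (1.51) and PFKFB3 (1.62), with adjusted p = 0.24 with an estimated correlation. Adjusted over the list alone these counts were unchanged. Of 30 genes of the unfolded protein and amino acid stress response, 18 rose, among them VLDLR (2.15) and the serine synthesis gene PSAT1 (1.51), with adjusted p = 0.758 with an estimated correlation. Of 17 immediate early genes, 12 rose, among them NR4A1 (0.95) and KLF10 (1.02), with adjusted p = 0.523 with an estimated correlation. Of 32 direct MYC targets, 18 rose and 3 fell, with TERT at 1.65, RCC1 at 1.38, CDK4 at -0.52 and E2F2 at -0.69 (adjusted p = 0.758 with an estimated correlation; camera adjusted p = 0.0595 against wt). Of 19 MYC-repressed genes, 12 rose, led by NDRG1 (3.66) and ITGA6 (1.76), while ITGA1 was at -1.27 and PDGFRB at -0.83 (adjusted p = 0.523 with an estimated correlation; camera adjusted p = 0.247 against wt).

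Ribosome biogenesis genes did not shift as a list in M14 (camera adjusted p = 0.979), with 14 of 43 higher and 11 lower. FBL and BRIX1 rose by 0.45 and 0.77, while HEATR1 was at -1.01 and FTSJ3 at -1.83. In the MYC network 7 of 11 rose, with MXI1 at 2.38, MAX at 0.64 (-0.12 against wt, adjusted p = 0.55) and MGA at -0.53. Of 31 BMP ligands, receptors and antagonists 14 rose and 6 fell, with the co-receptor ENG at 1.36, SMURF1 at -0.90 and ACVR2A at -0.51, the last at 0.02 against wt (adjusted p = 0.891). Of 18 BMP response genes 9 rose and 2 fell, with GATA2 at 1.51, RUNX2 at 0.95, SKIL at -0.70 and ID1 at -0.50, which was 0.10 against wt (adjusted p = 0.609). In all, 8515 genes passed, 4414 higher and 4101 lower, of which 975 and 756 by at least 1 log2. Higher calls made up 51.8%, but 33.9% in the deposited values and 79.2% with centring on hybridization controls. The arrays of both groups did not overlap for 59.7% of genes, against 10% by chance. The poly-A spike RNAs were 1.49 log2 higher on the M14 than on the V11 arrays, their 3' to 5' difference was 1.464 against 2.302, and that of ACTB 0.2198 against 0.4154.

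Silencing in M2 cells asked which genes depend on MYC there; both groups lie in 1 normalized set. The insulin-like growth factor binding proteins IGFBP7 and IGFBP3 rose by 4.69 ± 0.14 and 4.19 ± 0.37, the activin subunit INHBA by 4.37 ± 0.28, the myosin kinase MYLK by 4.11, the chemokine CXCL8 by 4.06 and TGFB1I1 by 4.01. The fatty acid transporter SLC27A2 changed by -3.31 ± 0.24, the phosphatase PTPRZ1 by -3.20, SLC1A6 by -2.99, KISS1R by -2.96, EMSLR by -2.92 and the secreted peptide PROK2 by -2.86. In silenced cells levels lay below 5.346 for SLC27A2, SLC1A6, KISS1R, EMSLR and PROK2, and in scrambled cells for MYLK. The genes that make ribosomes fell almost together. Of 43 ribosome biogenesis genes, 42 fell and none rose, among them NOLC1 (-1.69) and NOB1 (-1.99), with a median of -1.34 (camera adjusted p = 6.55e-22; adjusted p = 0.129 with an estimated correlation).

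Of 34 mitochondrial ribosome and import genes, 33 fell, among them TOMM20 (-1.20) and MRPS2 (-1.40), and of 32 direct MYC targets 29 fell, among them TERT (-1.90) and RCC1 (-2.22). Of 24 nucleotide synthesis genes 20 fell, among them IMPDH1 (-1.26) and IMPDH2 (-1.38). Each of these 3 lists had adjusted p = 0.129 with an estimated correlation. Cytosolic ribosomal protein genes fell by less, with 28 of 42 down and a median of -0.229. RPL36 changed by -1.11 and RPL29 by -0.63 (list adjusted p = 0.235 with an estimated correlation). Of 34 mitosis genes 21 fell, or 22 adjusted over the list alone, among them AURKB (-0.93), with adjusted p = 0.235 with an estimated correlation. Of 22 glycolysis genes 10 fell and 2 rose, with PFKM at -1.20 and GPI at -0.63 (adjusted p = 0.381 with an estimated correlation). PKM and PFKL rose by 0.29 and 0.27, but were at -0.09 and 0 with centring on hybridization controls.

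Matrix, inflammatory and interferon genes rose. Of 35 TGF-beta response and matrix genes, 32 rose and none fell, among them the collagen COL1A1 (2.33) and SPARC (1.65), with a median of 1.65 (camera adjusted p = 1.82e-13; adjusted p = 0.0745 with an estimated correlation). Of 16 fibroblast and smooth muscle markers 13 rose, among them ACTA2 (1.78), and TWIST2 fell by 0.58 (adjusted p = 0.0745 with an estimated correlation). Of 23 NF-kB and inflammatory cytokine genes 18 rose, among them TNFAIP3 (2.35) and CCL2 (3.20), with adjusted p = 0.129 with an estimated correlation. Of 36 interferon response genes 26 rose, or 28 adjusted over the list alone, among them PSMB9 (1.86) and SP100 (1.16), while USP18 fell by 0.60 (list adjusted p = 0.28 with an estimated correlation). Of 18 antigen presentation genes 11 rose, among them ERAP1 (1.63), with adjusted p = 0.235 with an estimated correlation. Of 29 lysosome and autophagy genes 20 rose, among them LAMP2 (2.01) and CTSB (1.90), and UVRAG fell by 0.67 (adjusted p = 0.16 with an estimated correlation). Of 17 immediate early genes 10 rose, among them IER3 (1.63) and DUSP1 (2.12), with adjusted p = 0.235 with an estimated correlation.

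Of 19 MYC-repressed genes 12 rose (camera adjusted p = 0.00185), among them the cell cycle inhibitor CDKN1A (2.09) and ITGB1 (1.29), and CEBPA fell by 0.49. Of 23 p53 targets 13 rose and 2 fell (camera adjusted p = 0.0204), among them PLK2 (2.46), while AEN was at -1.19 and MDM2 at -0.86. Each had adjusted p = 0.129 with an estimated correlation. Of 13 pro-survival regulators 9 rose and 2 fell, among them BIRC2 (1.31), CFLAR (1.63) and API5 (-0.41) (camera adjusted p = 0.0175; adjusted p = 0.13 with an estimated correlation). The BMP lists did not pass camera. Of 31 BMP ligands, receptors and antagonists 13 rose and 7 fell, with FSTL1 at 1.22, ACVR1 at 1.22 and ACVR2B at -1.12. Of 18 BMP response genes 8 rose and 4 fell, with RUNX2 at 1.31, MSX2 at 1.15, DLX5 at -1.13 and GATA2 at -0.76; ID1, ID2 and ID3 differed by -0.13, -0.28 and 0.21 (adjusted p = 0.515, 0.348 and 0.221). In the MYC network MAX fell by 0.79, MLX fell by 0.47 and MXD3 rose by 0.70. In all, 7587 genes passed, 3925 higher and 3662 lower, of which 1027 and 741 by at least 1 log2. With only the 6 siRNA arrays the count was 10025. The poly-A spike RNAs were 1.63 log2 higher on the silenced than on the scrambled arrays. Higher calls made up 51.7%, but 28% with centring on hybridization controls. Arrays did not overlap for 73.7% of genes, against 10% by chance. The median SD between replicates was 0.0599 in scrambled and 0.0635 in silenced arrays, against 0.121 to 0.164 in the other groups. A larger share than in the clone comparisons therefore does not show a larger effect.

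**Figure D2:**
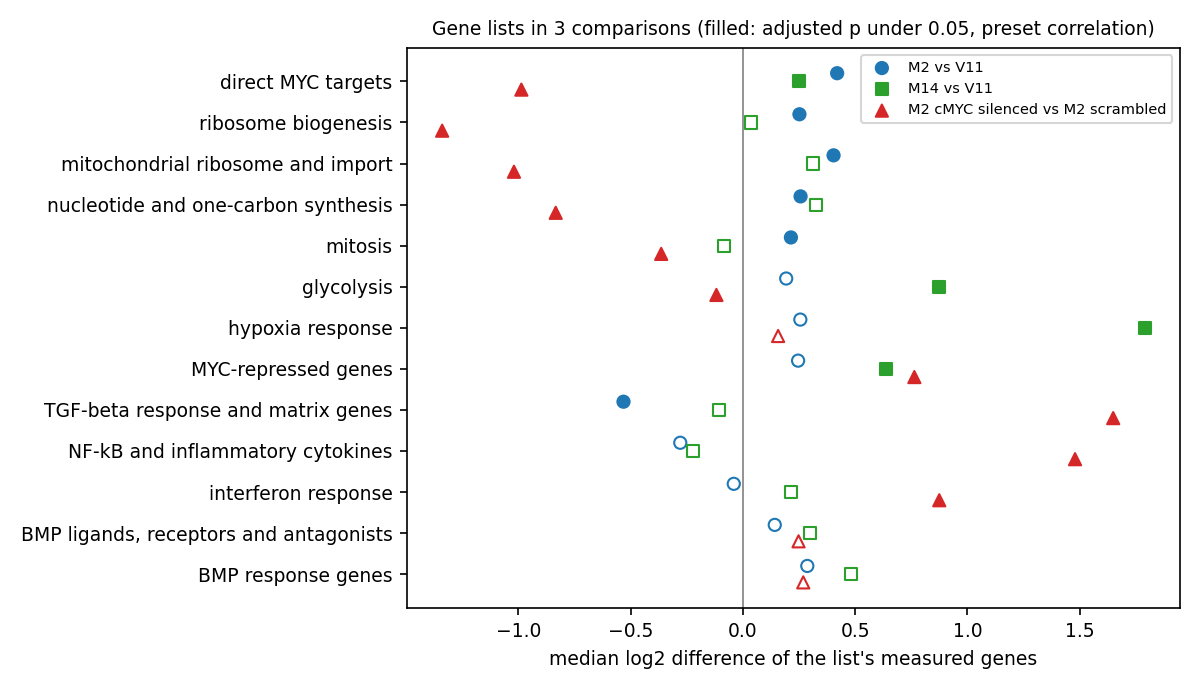
Median log2 difference of the measured genes of 13 lists in M2 against V11 (circles), M14 against V11 (squares) and on silencing (triangles); filled symbols passed camera at a preset correlation. Ribosome biogenesis had a median of -1.34 on silencing and the hypoxia response 1.79 in M14.

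Genes that moved the same way in both clones and the other way on silencing were then counted. The genes higher in both clones and lower on silencing were led by SLC1A6, with differences of 3.81, 4.74 and -2.99 in M2, in M14 and on silencing. KISS1R had 3.18, 5.23 and -2.96, the GABA receptor subunit GABRA5 3.67, 4.11 and -2.80, the lysophosphatidic acid receptor LPAR3 2.44, 3.24 and -2.48, FRMD3 4.06, 4.70 and -2.39, and the glycine decarboxylase GLDC 3.06, 2.77 and -2.37. In reverse, the adhesion molecule VCAM1 had -3.05, -3.65 and 3.22, CH25H -2.81, -3.13 and 3.36, GASK1B -3.79, -5.50 and 2.55, LRRC17 -2.44, -4.51 and 3.52, FILIP1L -2.59, -2.25 and 3.88, and the GABA transaminase ABAT -3.42, -2.15 and 3.95. SLC1A6 and KISS1R lay below 5.346 in V11 and silenced cells, GASK1B in both clones and scrambled cells, ABAT in M2 and scrambled cells, and VCAM1 and CH25H in scrambled cells. CH25H differed from wt by -0.38 in M2 (adjusted p = 0.445) and -0.71 in M14 (adjusted p = 0.136). GASK1B lay at 4.78 in M2 and 4.89 in wt, a difference that did not pass the test.

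In all, 1031 genes were higher in both clones and lower on silencing, and 1061 the reverse. If the genes that fell or rose on silencing were independent of the 2246 higher and 2261 lower in both clones, 580 and 626 would be shared. With centring on hybridization controls, 1326 genes in place of 2092 did so in either direction. Fewer genes passed there: 5165 in M2 against V11, 7867 in M14 against V11 and 6624 on silencing. The number that independent lists would share is not given for this setting, so the lower count does not show a weaker overlap. Of the 2 sets, 99 and 85 genes moved by at least 1 log2 in all 3 comparisons. Both clones moved 4507 genes the same way (542 by at least 1 log2 in both) and 685 oppositely, where independent lists share 2285 and 2284. With centring on hybridization controls 2846 moved the same way, again with no number for independent lists. Part of the excess may come from the shared V11 arrays, which cannot be divided into parts of 2. With wt in place of V11 on one side, so that no array was shared, 3245 and 3277 genes moved the same way, where independent lists share 2190 and 2105. Across genes, which are not independent replicates, the fold changes of the clones correlated with r = 0.624, and 68.6% had the same sign in both. Simulated unchanged groups with shared V11 arrays gave 0.5 and 66.6%. A shared control fixes these 2 values whatever the spread, so they are no measure for data with changed genes. The simulation called 0 genes the same way in both, and its covariance was 0.00976 against 0.271. It held only the spread between arrays, not differences particular to the V11 clone. M2 against V11 and silencing shared no array and moved 3306 genes oppositely (338 by at least 1 log2 in both), where independent lists share 2035, and 1075 the same way, with r = -0.375 across genes. With centring on hybridization controls 2063 moved oppositely, again with no number for independent lists. In M14 2973 genes moved oppositely to silencing, where independent lists share 2275, with r = -0.178. Higher calls in the mean of both clones made up 51.7% of 8260 genes (1051 by at least 1 log2), but 12.5% in the deposited values and 69% with centring on hybridization controls.

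**Figure D3:**
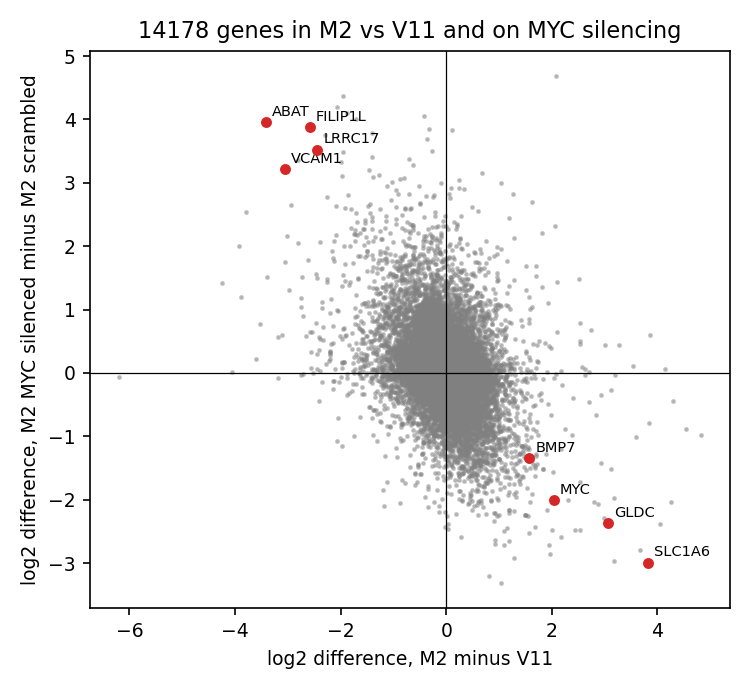
Each point is 1 of 14178 genes, with its log2 difference in M2 against V11 (horizontal) and on silencing (vertical); named genes are in red. BMP7, at 1.57 and -1.34, and MYC, at 2.03 and -2.00, lie at the lower right, and the genes correlate with r = -0.375.

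M14 against M2 compared the clones directly. PEG3 was 5.06 ± 0.19 higher in M14, ENPP2, which makes lysophosphatidic acid, 4.50 ± 0.32, the vitamin D hydroxylase CYP24A1 4.16 ± 0.26 and the growth hormone receptor GHR 4.11 ± 0.11. MAGEB2 differed by -4.92 ± 0.12, the matrix protein MGP by -4.87, SLC16A7 by -4.30 and IL13RA2 by -4.28. ENPP2, CYP24A1 and GHR lay below 5.346 in M2, and MAGEB2 and SLC16A7 in M14. Hypoxia response genes were higher in M14 for 18 of 20 (median 1.55; adjusted p = 0.244 with an estimated correlation), and glycolysis genes for 17 of 22 (adjusted p = 0.244 with an estimated correlation). Mitosis genes were lower for 19 of 34 (adjusted p = 0.484 with an estimated correlation), and ribosome biogenesis genes for 21 of 43 (adjusted p = 0.799 with an estimated correlation). MYC was 0.76 ± 0.24 higher in M14 (adjusted p = 0.0131), or 0.52 with centring on the median (adjusted p = 0.0769). BMP7 differed by -0.39 (adjusted p = 0.00651) in its brightest probe set but by 2.08 and 1.19 in 2 other probe sets, so its direction depends on the probe set. In all, 7797 genes passed, 4007 higher and 3790 lower, of which 733 and 329 by at least 1 log2. Higher calls made up 51.4%, but 89.3% in the deposited values, 85.7% with centring on hybridization controls and 35.2% with centring on the median. Arrays did not overlap for 55.6% of genes, against 10% by chance. The poly-A spike RNAs were at 8.37 on the M14 and 6.671 on the M2 arrays, their 3' to 5' difference at 1.464 and 2.464, and that of ACTB at 0.2198 and 0.5284.

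V11 against wt compared the empty-vector clone with untransfected cells. MAGEA8 was 5.92 ± 0.12 higher in V11, the BMP antagonist CHRDL1 4.35 ± 0.34, ALPK2 3.84 ± 0.28 and GASK1B 3.68 ± 0.26. Lower were NELL2 (-4.02), CXCR4 (-3.98), the cholinesterase BCHE (-3.84) and PLCB1 (-3.37). The 4 higher genes lay below 5.346 in wt and the 4 lower ones in V11. MYC differed by -1.08 ± 0.24 (adjusted p = 0.00253), or adjusted p = 0.0512 with only these 6 arrays, and BMP7 by -0.06 (adjusted p = 0.715). MAX fell by 0.76, and ID1, ID2 and ID3 rose by 0.59, 0.74 and 0.44. Of 36 interferon response genes 20 fell and 1 rose (adjusted p = 0.967 with an estimated correlation), and of 23 NF-kB and inflammatory cytokine genes 13 fell (adjusted p = 0.731 with an estimated correlation). In all, 5163 genes passed, 2728 higher and 2435 lower, of which 256 and 239 by at least 1 log2. With centring on hybridization controls 2686 passed, 886 higher and 1800 lower. Higher calls made up 52.8%, but 78.2% in the deposited values and 33% with centring on hybridization controls. Arrays did not overlap for 44.2% of genes, against 10% by chance.

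Scrambled siRNA against M2 compared transfected with untransfected M2 cells. The cancer-testis gene SPANXB1 differed by -9.58 ± 0.15, the pluripotency-associated gene DPPA4 by -6.77 ± 0.13, NNMT by -5.55 and SRGN by -4.88. GALNT13 was 4.99 ± 0.12 higher, WDR72 4.79, PEG3 4.44 and MDGA2 3.26. SPANXB1, DPPA4 and SRGN lay below 5.346 in scrambled cells, and GALNT13, WDR72 and MDGA2 in M2. Cholesterol synthesis genes fell, with 17 of 19 lower, and ribosome biogenesis genes rose, with 25 of 43 higher (each adjusted p = 0.898 with an estimated correlation). Replication genes rose for 16 of 38 and interferon response genes for 21 of 36 (each adjusted p = 0.898 with an estimated correlation). MYC was 0.95 ± 0.24 higher in scrambled cells (adjusted p = 0.00282). BMP7 differed by -0.04 (adjusted p = 0.775) in its brightest probe set and by 2.34 and 1.53 in 2 other probe sets. In all, 8697 genes passed, 3833 higher and 4864 lower, of which 608 and 938 by at least 1 log2. Higher calls made up 44.1%, but 98.1% in the deposited values and 89.5% with centring on hybridization controls. Arrays did not overlap for 74% of genes, against 10% by chance, with a median SD between replicates of 0.0599 in scrambled and 0.123 in M2 arrays. The 3' to 5' difference of the poly-A spike RNAs was 1.581 on the scrambled and 2.464 on the M2 arrays, and that of ACTB 0.08747 and 0.5284.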

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

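The tests of the poly-A spike RNAs, of the scaling and of M14 cells among the genes apart on the siRNA arrays, and of scaling, processing set and culture for the hypoxia genes were chosen after the results were seen; those of other splits of the arrays, of the processing set shared with M14 and of single M14 arrays were written before. Some of the tests chosen afterwards were also corrected after their first output.

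The clones differed from each other, tested directly as M14 against M2: 7797 genes changed, or 55% of those tested. Of 92 genes named in the clone comparisons, 56 differed between the clones, and 4 had opposite signs past the threshold. The 92 include 8 named for the largest differences between the clones, so the 56 is not a share to set against 55%. Higher in M14 were FRMD3 (0.65), MAGEA8 (1.22), KISS1R (2.04), CXCR4 (1.24), PEG3 (5.06), SLC1A6 (0.92), ENPP2 (4.50), CYP24A1 (4.16), GHR (4.11), LPAR3 (0.80), ABAT (1.27), MYC (0.76), MYCN (0.41), BMP2 (0.55), ID3 (0.42), MXI1 (0.91), TERT (0.36), ITGA6 (1.00), MRPS30 (0.37), TIMP3 (0.62), ACTA2 (1.03), COL5A2 (1.20), TWIST2 (0.29), RCC1 (0.46), NDRG1 (3.42), BRIX1 (0.29), GPI (0.34), PFKFB3 (0.69), ENG (0.74), RUNX2 (0.54), VLDLR (1.13), CA12 (1.74), BNIP3 (1.63), NR4A1 (0.56) and KLF10 (1.57). Lower in M14 were CYYR1 (-0.29), SLC16A7 (-4.30), DCAF4L2 (-4.14), SEMA3C (-1.79), MYOCD (-1.01), GASK1B (-1.72), IL13RA2 (-4.28), MAGEB2 (-4.92), MGP (-4.87), LRRC17 (-2.07), BMP7 (-0.39), ITGA1 (-0.49), WDR12 (-0.50), FBL (-0.17), FTSJ3 (-0.99), AURKA (-0.87), MSX1 (-0.27), NSDHL (-0.88), MGA (-1.06), E2F2 (-0.74) and HEATR1 (-0.69). The value of BMP7 is that of its brightest probe set; 2 others were at 2.08 and 1.19, so its direction depends on the probe set. The lists that differed, with their median, were the hypoxia response (1.55), immediate early genes (0.774), the unfolded protein and amino acid stress response (0.654), MYC-repressed genes (0.572), glycolysis (0.562), antigen presentation (0.499), TGF-beta response and matrix genes (0.417), DNA replication (-0.27), ribosome biogenesis (-0.266) and mitosis (-0.227). All 10 calls were lost with an estimated correlation, with adjusted p = 0.244, 0.476, 0.799, 0.476, 0.244, 0.476, 0.498, 0.871, 0.799 and 0.484 in the same order.

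The poly-A spike RNAs, control RNAs outside the genes compared, were 1.63 log2 higher on the silenced than on the scrambled arrays (SD 0.14; exact p = 0.1, the lowest that 3 against 3 arrays allow) and 1.49 higher on the M14 than on the V11 arrays (SD 0.093). Scaling of the arrays is argued against by the hybridization controls, which differed by 0.3 and -0.24. Less RNA per cell with less MYC may account for the 1.63, but the labels do not give how the spikes were added. In M14, which has more MYC than V11, it would give lower spikes, so it alone cannot account for the 1.49. That does not decide the 1.63, since another amount of spike RNA on the M14 arrays could give the 1.49. The spikes were at 6.756 in wt and 8.581 in silenced arrays, with MYC at 9.44 and 9.34. They were at 6.877 in V11 and 6.671 in M2, with MYC at 8.36 and 10.40. If spikes were added alike to these groups, this argues against the level of the MYC probe set alone. These groups cross normalized sets. Another amount of spike RNA cannot be told apart from less RNA of the cells, since the 4 spikes moved together, by at least 1.52 and 1.27. A difference in RNA amount between these groups stays open.

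Some genes set both siRNA groups apart from wt, V11 and M2 by 3 log2 or more: CTSZ, DPPA4, MID1, SPANXB1 and SRGN were lower and CDH12, GALNT13 and WDR72 higher, 8 in all, named after their values were seen. M14 cells on the siRNA arrays are argued against, since over 118 genes that differ between M14 and M2 the scrambled arrays were nearer M2 for 83.9%. Of the 8 genes, 87.5% stayed 2 log2 apart under every scaling. They were picked for a gap of 3 log2 or more, while the deposited values moved the median gene by 1.13 in scrambled siRNA against M2. The outcome was therefore nearly fixed by the choice of genes. It shows only that most of these gaps exceed the differences between the scalings used. A processing set shared with M14, which also had lower 3' to 5' differences of spikes and ACTB, is argued against. M14 lay nearer wt, V11 and M2 for 100% of the 8 genes. Another line, subclone or passage, and the transfection itself, were not tested and stay open.

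The hypoxia response list was higher in M14 than in V11 with a median of 1.79 (adjusted p = 0.24 with an estimated correlation). Scaling and a single M14 array are argued against, since the lowest medians were 1.6 over the scalings and 1.6 without 1 M14 array. A processing set shared with the siRNA arrays, meaning their lower 3' to 5' differences of spikes and ACTB, is argued against. The list was at -0.182 in scrambled siRNA against M2, which differ in these. The higher spikes were shared by M14 (8.37) and silenced arrays (8.581) but not by scrambled ones (6.946). A processing feature that goes with the spikes was therefore not tested. Denser or less oxygenated M14 dishes could give the same 1.64 that M14 had against wt, and cannot be told apart from a property of the clone, since no label separates them.

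Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. A split that mixes the groups also puts any difference between them, whatever its cause, into the spread. Such splits call few genes, so the gene counts below do not show why the groups differ. Only 1 of the 10 splits, the real one, gave as many changed genes in each: 7607 against a highest other of 0 in M2 against V11, 8515 against 18 in M14 against V11, 7587 against 0 on silencing, 7797 against 255 in M14 against M2, 5163 against 2 in V11 against wt and 8697 against 0 in scrambled siRNA against M2. Other splits shifted as many lists. In M2 against V11, 5 of the 10 splits shifted at least the real 8, with a highest other of 10. In M14 against V11 it was 10 of 10 (real 6, highest other 12), on silencing 5 (17 and 18), in M14 against M2 8 (10 and 14), in V11 against wt 10 (2 and 10) and in scrambled siRNA against M2 7 (4 and 8).

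Of the 84 splits of the 9 arrays of V11, M2 and M14 into 6 and 3, 2 gave as many genes as V11 against both clones as 1 group (6083). The other was M14 against M2 and V11 with 6344, so M14 stands apart by as many genes as V11 does. M2 against M14 and V11 gave 4322. Splits that mixed the groups gave 549 at most, so any whole group would stand out. The test therefore cannot decide whether the difference from V11 is particular to the MYC-transfected clones. Of 100 regroupings drawn from 840, 1, the real one, gave as large an overlap of the clones (4507; highest other 4235). The highest others compared mixed arrays with M14 whole (4235) or with V11 whole (4106), and the highest with no group whole in that place was 10. Mixed groups called almost no genes, so this test does not show an overlap particular to the 2 clones. The opposite overlap of M2 against V11 with silencing (3306; highest other 0) and the overlap of all 3 comparisons (2092; highest other 0) were each reached by 1 of 100. The other splits called too few genes to overlap, so these counts do not show whether the overlaps exceed those of independent lists.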

How the results depend on the processing

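All 16 counts stayed within 1.5 times of those reported with trend and robust settings, only the arrays compared or a replicate block, 15 of 16 with the mean of probe sets, no filter, the stricter filter, centring on the median or 1 weight per group, 12 of 16 in the deposited values and 10 of 16 with centring on hybridization controls. None of the 10 did with at least 1 log2 required or with each probe set on its own, which change the number of genes by construction, and none of the 6 list counts did with an estimated correlation. The shares of higher calls moved widely with the scaling, from 50.1% to 5.06% in M2 against V11 and from 51.4% to 89.3%, 85.7% and 35.2% in M14 against M2. Values that reversed, and changed counts and MYC and BMP7 values, are given by setting, other changes as counts; the cause was not tested unless a setting's construction gives it. Of 255 differences of named genes, 15 no longer passed the test, 8 newly passed and 3 reversed with centring on hybridization controls, and 4, 8 and 6 in the deposited values. Of 124 with wt in place of V11 it was 14, 3 and 8, of 247 with the mean of probe sets 7, 2 and 2, and of 4572 without 1 array 26, 12 and 0. The 192 list tests held 47 calls, all lost with an estimated correlation. Calls lost and gained were 5 and 18 with centring on hybridization controls and 9 and 24 in the deposited values. They were 0 and 12 with centring on the median and 3 and 7 with the mean of probe sets. Over 64 list tests with wt in place of V11, 3 calls were lost and 4 gained. Over 3456 list tests without 1 array, 24 calls were lost and 42 gained. Signal near background limits the genes that could be tested. With the mean of all probe sets of a gene, BMP7 differed by 0.73 in M14 against M2 and by 0.91 in scrambled siRNA against M2, and 4 lists shifted in V11 against wt. With no filter, the correlation across genes of M2 against V11 with silencing was -0.35 and 10 lists shifted in M14 against V11. With the stricter filter they were -0.412, and 4 lists in V11 against wt. With only the arrays compared, MYC differed by -1.08 in V11 against wt (adjusted p = 0.0512). With at least 1 log2 required, genes changed numbered 1041 in M2 against V11, 1731 in M14 against V11, 1768 on silencing, 1062 in M14 against M2, 495 in V11 against wt, 1546 in scrambled siRNA against M2 and 1051 in the mean of the clones; 542 were shared by the clones, 338 moved oppositely in M2 and on silencing, and 184 did so in both clones. With each probe set on its own, the same counts were 16042, 17940, 15666, 16984, 10486, 19713, 17214, 8901, 6388 and 3806. Centred on hybridization controls, 2686 genes changed in V11 against wt, the 3 overlaps were 2846, 2063 and 1326, BMP7 differed by -0.10 in M14 against M2 and 0.56 in scrambled siRNA against M2, PKM was at -0.09 and PFKL at 0 on silencing, and 15 lists shifted in M2 against V11 and 7 in scrambled siRNA against M2. With wt in place of V11, the correlation was -0.466. MAGEA8 in M14 was at 0.95, MAX at -0.29 in M2 and -0.12 in M14, ID2 in M2 at 0.65, ID1 in M14 at 0.10, IMP4 in M2 at 0.24, IMPDH2 in M2 at 0.56 and ACVR2A in M14 at 0.02; V11 against wt has no such alternative. With an estimated correlation, camera found 0 lists in M2 against V11, 0 in M14 against V11, 0 on silencing, 0 in M14 against M2, 0 in V11 against wt and 0 in scrambled siRNA against M2. Fry found 21, 23, 25, 18, 7 and 20. Without an array, the lists shifted in M2 against V11 ranged from 5 (without V11 replicate 2) to 10 (without M14 replicate 2), and in scrambled siRNA against M2 from 3 (without M2 replicate 3) to 7 (without M14 replicate 2). The remaining settings were chosen after seeing the data. In the deposited values, 11750 genes changed in M2 against V11 and 13750 in scrambled siRNA against M2. BMP7 was at 0.03 in M14 against M2 and 1.19 in scrambled siRNA against M2, MAX at -0.07 in M2, and BMP6, ID2 and ID3 at 0.35, 0.54 and 0.45 in scrambled siRNA against M2; 4 lists shifted in V11 against wt and 11 in scrambled siRNA against M2. Centred on the median, MYC differed by 0.52 in M14 against M2 and 7 lists shifted in scrambled siRNA against M2, as did 7 with 1 weight per group. The other BMP7 probe sets gave 2.08 and 1.19 in M14 against M2 and 2.34 and 1.53 in scrambled siRNA against M2, and the weakest gave 0.11 in M2, 0.13 in M14 and 0.02 in M14 against M2.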

Other observations

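All genes of this part were chosen after their values were seen, and both hypotheses and their tests were written after the results were seen. Single genes of neural lineages moved, while their lists did not pass camera. OLIG2, a transcription factor of oligodendrocyte precursors, was 2.87 ± 0.15 higher in M2 and 3.07 ± 0.15 higher in M14 than in V11 and changed by -2.07 ± 0.15 on silencing. The proteoglycan gene CSPG4 had -0.51, 1.16 and 2.95, and the stem cell filament gene NES was at -1.56 in M2, 0.27 in M14 (adjusted p = 0.358) and 2.03 on silencing. Of 14 glia and neural stem markers, 3 rose and 3 fell in M2, 6 and 4 in M14 and 5 and 5 on silencing (camera adjusted p = 0.966, 0.293 and 0.844). The synaptic gene SNAP25 was at -2.71 in M2, 0.42 in M14 (adjusted p = 0.083) and 0.89 on silencing. Of 22 neuron and granule neuron precursor markers, 2 rose and 9 fell in M2, 6 and 5 in M14 and 7 and 4 on silencing (camera adjusted p = 0.112, 0.767 and 0.844).

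Single genes of the SHH and WNT pathways moved, while their list did not pass camera. WNT5A, a secreted ligand, changed by 2.82 ± 0.21 on silencing and -0.92 ± 0.21 in M2, and differed by -0.48 in M14 (adjusted p = 0.0589). The beta-catenin gene CTNNB1 changed by 1.09 on silencing, -0.79 in M2 and -0.19 in M14. The WNT antagonist DKK3 was higher in all 3, by 0.33, 1.90 and 2.91, while SFRP1 had 0.98, 1.13 and -0.94 and the hedgehog receptor gene PTCH1 0.56, 0.48 and -0.47. Of 27 SHH and WNT pathway genes, 11 rose and 9 fell in M2, 12 and 4 in M14 and 13 and 7 on silencing (camera adjusted p = 0.614, 0.211 and 0.12).

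The first hypothesis was that the level of MYC alone sets that of ribosome biogenesis genes. Its test was rewritten after its first values were seen, and is relative to the median gene, which a constant factor per array cannot move. Over the 9 pairs of a silenced and a wt array, the median of the list lay between -0.80 and -0.53 in quantile-normalized values and between -0.77 and -0.55 in the deposited values. In quantile-normalized values MYC lay between -0.60 and 0.42 on these pairs. The list was below -0.50 also in pairs with more MYC in silenced cells, which argues against the level of this MYC probe set alone. The 9 pairs reuse 3 arrays of each group, and the sign of MYC depended mostly on the wt array, at 9.02 to 9.94. Since the probe set may not detect the transgene, the hypothesis about MYC itself is not decided. The stock of the cells, the transfection and a processing difference that is not the same for all genes were not separated. The other hypothesis was that the lower MYC of V11 moves genes as silencing does. The fold changes of V11 against wt and of silencing correlated with -0.109 across genes, which are not independent. Across all genes V11 thus did not move as silenced cells did. V11 against wt also holds effects of the vector, selection and cloning and crosses normalized sets. The correlation therefore cannot decide whether the lower MYC of V11 contributes.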
